A study of Mus musculus with 8 samples.

How the data were processed

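Gene expression was measured on 6 Affymetrix arrays of mouse ES-cell-derived hematopoietic progenitors, 2 each for the groups MigR1, HoxB4 and iHoxB4. Binding of Flag-tagged HoxB4 was measured by chromatin immunoprecipitation on 2 Agilent promoter arrays (ChIP-chip), each with another set of probes, so that every promoter region has 1 sample and no replicate. Groups and replicate numbers come from the labels. The labels do not say whether the 2 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

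The expression values are a deposited score per probe set. Affymetrix Expression Console and RMA are named in the submitters' processing notes, with no version. The deposited score ran from 16.9 to 86, and the distribution was nearly the same on all 6 arrays, with a median of 45.43 on each. Log2 RMA values do not reach such numbers. The median replicate SD rose from 0.586 at the lowest scores to 0.764 for scores from 35 to 45 and fell to 0.202 above 75, unlike that of a linear intensity, so the scale is unknown and no fold change of expression is given. The design, fixed before the data were examined, asked for log2 of values that are not on the log2 scale. The test was therefore run on log2 of the deposited score, a choice settled after the counts on both scales had been seen, and levels are reported in score units. Annotation pairing probe sets with genes was not used here. Expression results are therefore for unnamed probe sets, the gene lists were not tested on expression, HoxB4's own transcript was not checked, and expression was not joined with binding. No more than 2 probe sets with a higher and 2 with a lower score are named, those with the largest change in HoxB4 whose groups did not overlap. The fixed rule for named genes asked for the 10 largest changes each way.

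Of 35557 probe sets, 27329 lay above the 25th percentile of an array on at least 2 arrays and were tested. A linear model with 1 mean per group over all 6 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. The prior degrees of freedom were 1.5. On simulated data of the HoxB4 comparison with 27329 probe sets, 0% of probe sets changed by 0.05 on the log2 scale were recovered, 22% of those changed by 0.1, 74% of those changed by 0.2 and 90% of those changed by 0.4, with 3 false calls among 96. For the iHoxB4 comparison the shares were 2%, 18%, 78% and 94%, with 5 false calls among 101. In these simulations all arrays had the same spread for a probe set. The real MigR1 arrays varied more, with a median replicate SD of 0.611 score units against 0.325 in HoxB4 and 0.305 in iHoxB4. The recovery simulations therefore did not measure the share of false calls under such unequal spread. Both comparisons against MigR1 share the MigR1 arrays, so unchanged groups were simulated 50 times against shared controls, with the spread scaled for each group. The number of arrays limits the precision.

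For ChIP-chip, the red channel (Cy5) held Flag-IP DNA and the green channel (Cy3) input DNA, per the labels. The intensities are processed signals from Agilent Feature Extraction 10.1.1.1, which subtracted background, removed spatial trends and scaled each dye by 1 linear factor, per the file headers. Mean and background intensities deposited in the same files served an alternative. The deposited log10 ratio column and the deposited value tables, on the log10 scale with medians of 0.0181 and 0.0207 and therefore not centred, were further alternatives. Both channels were well above background for 95.3% of probes on each array, and no probe was saturated. The genome build of the probe coordinates is not given in the sources used here.

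Log2 of Flag-IP over input was computed for 237195 and 237185 probes and centred on the median of each array (0.06 and 0.07 before centring), leaving out control spots and 19 and 38 probes with outlier marks. No loess or quantile step was applied. The median over 3 neighbouring probes whose starts lay at most 1000 bp apart gave 425939 windows. The threshold was the lowest value, from 0.5 in steps of 0.1, at which depleted windows numbered at most 5% of enriched ones. On 60000 simulated probes in a self-test, 32.3% of 198 planted regions with a log2 ratio of 1 were recovered, and 100% of those with a ratio of 2 or 3. Beside them were 2, 23 and 23 regions that had not been planted. The simulated noise was symmetric and independent between probes, whereas neighbouring probes of the arrays correlated at 0.59. The threshold was 1.3, 1.1 and 1.1 in the simulations but 4.6 on the arrays, so these recovered shares do not hold for the arrays. Genes were taken from the annotation in the files and renamed through RefSeq tables of assembly GRCm38.p6, used for names alone. Of 16908 symbols, 16330 were matched by accession, 279 by symbol and 164 by synonym, and 135 were kept as in the files.

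A gene's signal is its highest window. The gene lists, 28 in all, were fixed before the data were examined. Each list's median was ranked among 10000 random lists of the same size, matched on number of windows and input signal. With 1 array per probe set this ranking describes these arrays and carries no p-value. Over-representation of the lists among enriched genes was tested with Fisher's exact test, two-sided, over the 16655 genes with windows, which compares genes on these arrays and not replicate samples. The named genes are the 10 with the highest windows and Hoxb4, members of the lists at or above a log2 ratio of 2, and members of the lists of stem cell regulators, Hox genes, stroma, endothelium and sex-linked genes. Members of other lists below 2, and gene families sharing a symbol stem, were chosen as examples after their values were seen. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

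Alternatives fixed beforehand covered the replicate number as a block, the arrays in the fit, the variance trend, the filter, further normalization, thresholds on the ratio of scores, single arrays left out, the background correction, window and threshold of the ChIP data, and dim probes. Added after seeing the data were the score without log2, array weights, a crossed block, leaving out the first 6614 probe sets (consecutive numbers), removal of the brightness trend from the log ratios, list tests at a log2 ratio of 2, and list rankings under other signal measures.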

Results

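Expression and HoxB4 binding were measured in blood progenitors made from mouse embryonic stem (ES) cells. HoxB4 is a homeobox transcription factor that promotes expansion of blood stem and progenitor cells in culture. Cells with the surface proteins c-Kit, the receptor for stem cell factor, and CD41, an early blood lineage marker, were taken from embryoid bodies at day 6 and grown on OP9, a bone marrow stromal cell line. The MigR1 group (n = 2 arrays) carried a control retrovirus and the HoxB4 group (n = 2) a HoxB4 retrovirus, both without doxycycline. The iHoxB4 group (n = 2) was grown with doxycycline, so the drug and the way HoxB4 was delivered differ along with the group. Per the labels the RNA came from day 8 of coculture, whereas the series design text names day 12 for both assays. Binding was measured on 2 promoter arrays, 1 array for each of 2 probe sets, with Flag-IP DNA against input DNA from cells expressing Flag-tagged HoxB4.

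The first comparison asked which transcripts differ when progenitors carry HoxB4 in place of the control virus. In the HoxB4 group 1296 probe sets had a higher score and 1712 a lower score than in MigR1, together 11% of 27329 tested (limma, adjusted p under 0.05). At an unadjusted p under 0.05 the balance was the other way, with 4061 higher and 3299 lower. Of the probe sets tested, 18.4% belonged to the first run of consecutive numbers. That run held 106 of the higher calls (8.18%) and 125 of the lower calls past the adjusted threshold. Annotation was not used, so whether this run measures transcripts of genes was not determined here. Leaving the run out gave 1738 higher and 1899 lower probe sets. The largest increase was at probe set 10461735, from 34.2 ± 0.341 (SD, n = 2) in MigR1 to 56.9 ± 0.544 (SD, n = 2) in HoxB4 (limma adjusted p = 0.000554). Probe set 10605034 rose from 30.2 ± 0.343 to 45.2 ± 0.992 (limma adjusted p = 0.000905). The largest decrease was at probe set 10419151, from 64.5 ± 1.08 to 31.5 ± 2.1 (limma adjusted p = 0.00234), and probe set 10589535 fell from 71.2 ± 1.69 to 39.8 ± 0.638 (limma adjusted p = 0.000846). Among probe sets that passed, the median change on log2 of the score was -0.11 for lower and 0.07 for higher ones. The scale of the score is unknown, so these sizes do not show that decreases of expression were larger than increases. A difference of at least 5 score units was seen for 699 lower and 166 higher probe sets. All called probe sets had groups that did not overlap, as did 8335 higher and 5949 lower among all tested, together 52.3% against a chance share of 33.3%. The MigR1 arrays differed most from each other, with a median replicate SD of 0.611 score units against 0.325 in HoxB4 and 0.305 in iHoxB4, and MigR1 array 1 correlated across probe sets with iHoxB4 array 2 (0.9909) as well as with MigR1 array 2 (0.9895). The files do not pair probe sets with genes, so the transcripts stay unnamed. Leaving out HoxB4 array 1 left 94 higher and 477 lower probe sets, leaving out HoxB4 array 2 left 123 and 518, and leaving out either iHoxB4 array left 213 and 747.

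**Figure D1:**
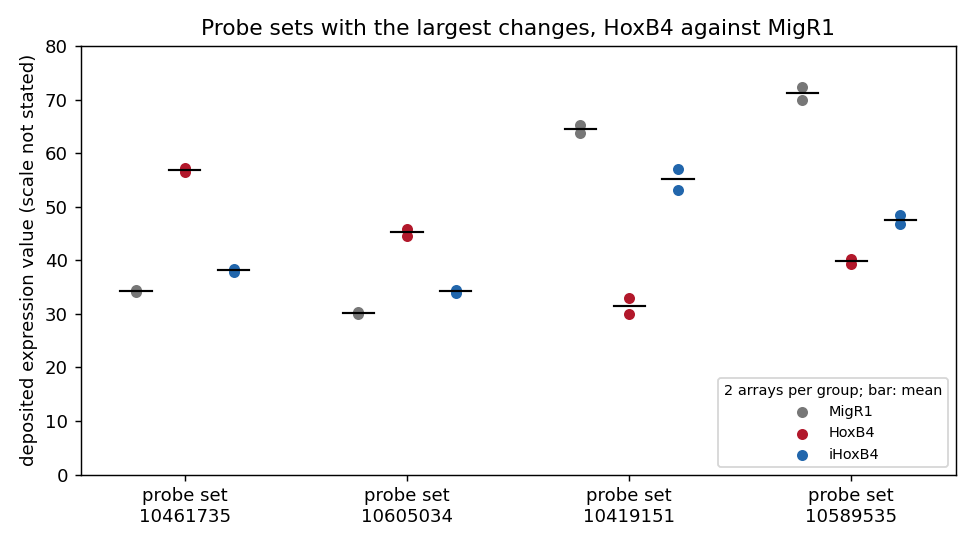
Deposited expression score (vertical axis, scale not stated) of the 4 named probe sets on each of the 6 arrays. Points are single arrays and bars group means (n = 2), and iHoxB4 lies between MigR1 and HoxB4 at all 4, which were picked for their large change in HoxB4.

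The second comparison asked the same of iHoxB4 cells. Against MigR1, 244 probe sets were higher and 725 lower in iHoxB4, together 3.55% of those tested (limma, adjusted p under 0.05). At an unadjusted p under 0.05 the counts were nearly even, 2997 higher and 3030 lower. The first run of consecutive probe set numbers held 68 of the higher calls (27.9%) and 28 of the lower calls past the adjusted threshold. Leaving the run out gave 428 higher and 1025 lower probe sets. Probe set 10589535 again fell, to 47.6 ± 1.26 (SD, n = 2; limma adjusted p = 0.00869). Probe sets 10461735 and 10605034 rose to 38.1 ± 0.368 (limma adjusted p = 0.0179) and 34.2 ± 0.395 (limma adjusted p = 0.0286). Probe set 10419151, at 55.1 ± 2.77, did not pass (limma adjusted p = 0.124). These calls rest on the spread pooled over all 6 arrays: with either HoxB4 array left out no probe set passed (smallest limma adjusted p = 0.0583), though 2284 were higher and 2536 lower at an unadjusted p under 0.05. With iHoxB4 array 1 or 2 left out none passed either. Calls remained when a MigR1 array was left out, but a lone array adds no spread to the fit. The error then came from HoxB4 and iHoxB4 alone, whose arrays varied less than those of MigR1. Those fits are therefore no check of the calls.

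The changes in HoxB4 and iHoxB4 overlapped. Past the threshold in both were 859 probe sets with the same direction, 174 higher and 685 lower, and 2 with opposite directions. Independent lists of these sizes would share 11.6 higher and 45.4 lower probe sets, and simulated unchanged groups sharing the MigR1 arrays, which had few calls at all, shared 0.06 on average, 1 at most. Of the iHoxB4 calls, 71.3% of higher and 94.5% of lower probe sets were also called in HoxB4. Across probe sets, which are not independent replicates, the changes correlated at r = 0.79, against 0.78 for unchanged groups with shared controls, and 77.6% had the same sign, against 78.4%. Their covariance was 0.00267 against a simulated 0.000776, a difference of 0.00189. The MigR1 arrays cannot be split with 2 left in each part, so part of the overlap may come from these shared controls. With any HoxB4 or iHoxB4 array left out no overlap remained, because iHoxB4 then had no calls. An overlap remained without a MigR1 array, but those fits hold no MigR1 spread and are no check of it.

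The third comparison set the HoxB4 groups against each other. In iHoxB4, 279 probe sets were higher and 140 lower than in HoxB4 (1.53% of those tested; limma, adjusted p under 0.05). Probe set 10419151 was 23.6 score units higher in iHoxB4 (limma adjusted p = 0.0159) and probe set 10461735 lower by 18.8 units (difference -18.8; limma adjusted p = 0.00525). Of the 1712 probe sets lower in HoxB4 than in MigR1, 270 were higher in iHoxB4 than in HoxB4 and 2 were lower. Of the 1296 higher in HoxB4, 128 were lower in iHoxB4 and 0 were higher. Both sets were chosen on the HoxB4 arrays that this comparison uses again, which favours these directions. The first principal component (49.9% of variance) placed MigR1 at -4.52 and -7.41, iHoxB4 at 0.462 and 1.76, and HoxB4 at 5.26 and 4.45. The second component (25.2%) set the MigR1 arrays apart from each other, at 5.84 and -4.51. With any HoxB4 or iHoxB4 array left out no probe set passed (smallest limma adjusted p from 0.115 to 0.163), though 1142 to 1430 were higher and 903 to 1132 lower at an unadjusted p under 0.05.

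**Figure D2:**
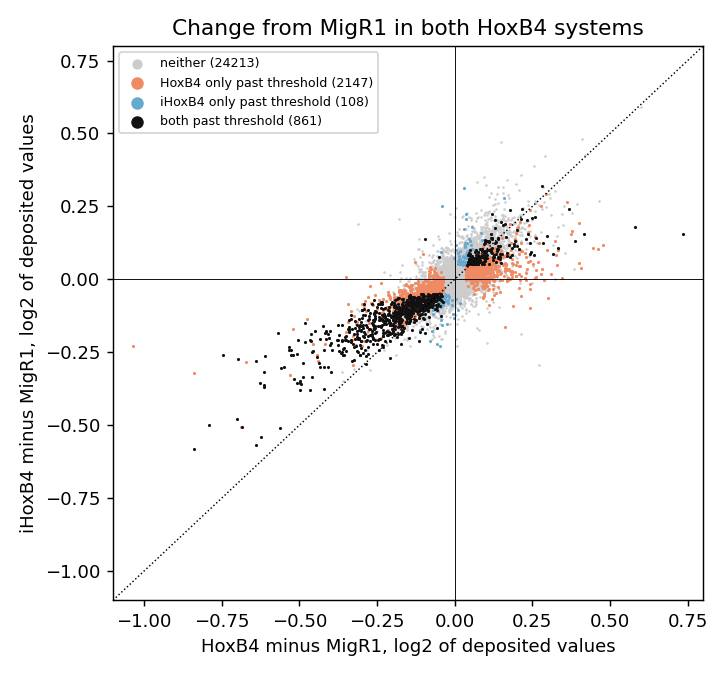
Change from MigR1 on log2 of the deposited score, HoxB4 (horizontal) against iHoxB4 (vertical), 1 point per probe set, coloured by which comparison passed the threshold (limma, adjusted p under 0.05). Most points past it in both lie in the lower left, where 685 probe sets were lower in both groups, and the dotted line marks equal changes.

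Binding was compared between Flag-IP and input DNA to ask which promoters HoxB4 occupies. The strongest signal was upstream of Atp6ap2, which encodes an accessory subunit of the vacuolar proton pump. Its highest window reached a log2 ratio of 4.84 (probes from 3.89 to 4.94) at -219 bp from the gene start, on chromosome X from 11744414 to 11744803. This was the single region, and Atp6ap2 the single gene, above the fixed criterion, which required a log2 ratio of 4.6. At 4.6 the criterion rested on 2 enriched windows against 0 depleted ones, and at 4.5 there were 2 of each. With limma's normexp, another background correction, the same criterion was met at 1.1 and gave 9102 regions and 7425 genes. That alternative started from mean intensities, without the spatial and dye steps of the processed signals, and added an offset of 50. The count thus depends on the signal processing, and which of these steps moved it was not tested. Next came Rtn4 (4.10), which encodes the neurite growth inhibitor Nogo, on chromosome 11 from 29592697 to 29592967, and Enkd1 (3.70) on chromosome 8 from 108597194 to 108597563. Zfp317, a zinc finger gene, had a window of 3.44 and Arid1a, which encodes a chromatin remodelling subunit, one of 3.41 lying at -3837 bp. Akr1e1, an aldo-keto reductase gene, reached 3.39 and Coq7, needed for ubiquinone synthesis, 3.34. Os9, which acts in degradation of misfolded endoplasmic reticulum proteins, reached 3.18, as did a window shared by Slc4a1ap and Supt7l. Astl, which encodes an egg protease, had 3.34, but not all of its probes were well above background, and its highest window was 1.86 over probes that were. The Hoxb4 promoter itself had a highest window of 0.66 (probes from 0.17 to 1.01), at percentile 31.5 of 16655 genes.

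At a fixed log2 ratio of 2, 526 genes had an enriched window, in 465 regions. Their highest window lay within 500 bp of the gene start for 52.1% of genes, against 17.6% of all windows. The second share is not over the highest window of each gene. That share for all genes is not given here, so the contrast is not particular to these genes. The mean log2 ratio was -0.33 upstream of genes, from -6000 to -4000 bp, and 0.43 over the first 250 bp of genes, with 0.46 on array 1 and 0.41 on array 2. Depleted windows at the same size were more numerous, 5539 against 1053 enriched ones. This direction turned with normexp (45 against 1691) and with the brightness trend of the log ratios removed (231 against 349), so the share of windows at 2 that is noise is not known. There was no replicate.

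**Figure D3:**
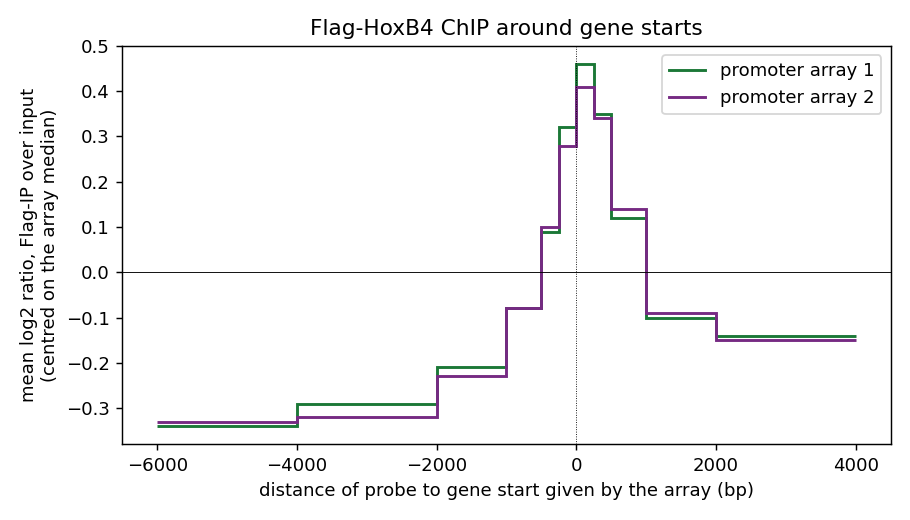
Mean log2 ratio of Flag-IP over input (vertical) by distance of the probe to the gene start in bp (horizontal), 1 line per promoter array. On both arrays the mean is highest over the first 250 bp, at 0.46 and 0.41.

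**Figure D4:**
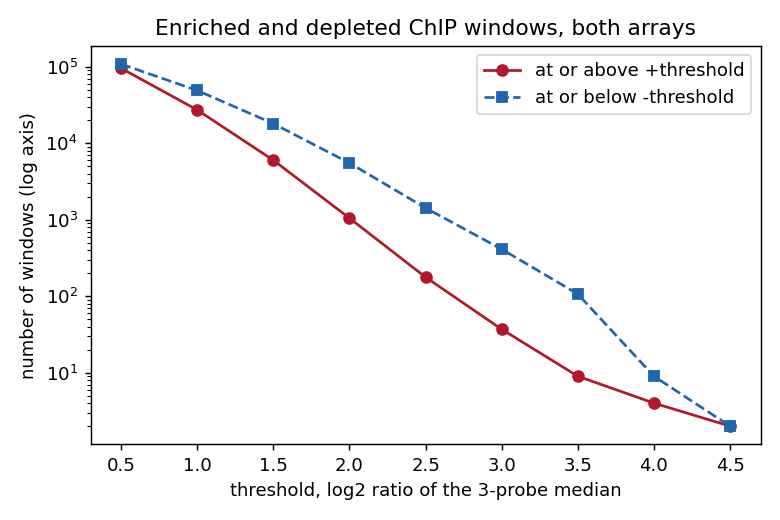
Number of windows (log axis) at or above a log2 ratio and at or below its negative, over both arrays. Depleted windows outnumber enriched ones up to a threshold of 4.0, with 5539 against 1053 at 2 in the main scaling, the one drawn.

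Stem cell regulators carried more signal than random genes of like window number and input signal, by the height of their highest window. Over 28 genes of that list the median highest window was 1.23, at percentile 97.8 of matched random lists, which had a median of 1.01. Lyl1, a blood bHLH factor, had a window of 2.12, the highest of the list, 2156 bp into the gene. The related factor Tal1 had 1.78, Runx1 1.57, Etv6 1.55 and Gata2 1.52, while Kit had 0.86, Myb 0.64 and Tek 0.19. Megakaryocyte and platelet genes stood at percentile 99.1, with a median of 1.41 over 19 genes. The highest were platelet factor 4 (Pf4, 1.99), the thrombin receptor gene F2rl2 (1.97), Gp9 (1.72) and Itga2b (1.71), which encodes CD41. Of these 19 genes 13 reached 1 and 0 reached 2, and the lowest were Clec1b (0.08) and Ppbp (0.71). Proliferation genes stood at 99.2 with a median of 1.37 over 29 genes, led by the mitotic checkpoint kinase genes Bub1 (2.14) and Bub1b (2.01). Cholesterol synthesis genes stood at 98.4, with a median of 1.35 over 17 genes, led by Insig1 (2.65) and Cyp51 (2.15). T and NK cell genes stood at 98.5 with a median of 1.02, below that of the stem cell list, and Gata3 was highest (1.85). The 5 sex-linked genes measured stood at 99.5, with Uty at 2.30 and Zfy1 at 0.09, but 3 of them also had a window at or below -2, namely Eif2s3y (-3.46), Zfy1 (-2.23) and Uty (-2.13), and probes of chromosome Y had a mean of -0.69. These 6 of 28 lists lay above the middle 95% of their random lists, where 0.7 lists of randomly drawn genes would, and 0 lay below. The random lists were not matched on promoter activity or sequence composition. Ribosomal protein (Rpl) and Mediator (Med) gene families, picked after seeing the data, stood at percentile 100. The ranks therefore do not tell HoxB4 binding from a general property of promoters.

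On this measure the other lists lay within that range. Hox genes and cofactors stood at percentile 91.9 with a median of 0.98 over 32 genes, from Hoxa6 (1.78) and Hoxd9 (1.76) to Hoxb3 (0.25). Interferon response genes stood at 97.2, ribosome biogenesis and MYC targets at 96.4 and TGF-beta and BMP signalling at 95.7, with Bst2 at 2.06, Fbl at 2.23 and Tgfb1 at 2.69. B cell genes stood at 94.9, with Blnk at 2.16 and Dntt at 2.14. Integrins and adhesion stood at 91.8, AP-1 and immediate early genes at 90.9, monocyte and macrophage genes at 88.7, and glycolysis and hypoxia at 87.0, where Gapdh reached 2.40, Eno1 2.38 and Pgam1 2.23. Cell cycle inhibitors stood at 85.5, cytokine receptors and JAK-STAT at 77.7, endothelial genes at 76.0 and ATF4 stress response genes at 74.6, with Sesn2 at 2.60. Neutrophil genes stood at 62.8, dendritic cell genes at 50.5, pluripotency genes at 46.7 and Notch signalling at 36.4, with Dll1 at 2.30. Erythroid genes stood at 28.3, Wnt signalling at 23.2, mesoderm and neural genes at 17.3 (Pax6 at 2.46), OP9 stroma genes at 14.9 and mast cell and basophil genes at 9.43.

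Other signal measures, chosen after seeing the data, moved some lists. As the mean over probes within 500 bp of gene starts, megakaryocyte genes stood at percentile 99.9 and proliferation genes at 99.4, but stem cell regulators at 78.4, cholesterol synthesis at 94.0, T and NK cell genes at 40.9 and sex-linked genes at 76.0. With the brightness trend removed, stem cell regulators stood at 99.2, T and NK cell genes at 97.8 and sex-linked genes at 99.9, but megakaryocyte genes at 94.8, cholesterol synthesis at 95.2 and proliferation genes at 71.6. With limma's normexp, cholesterol synthesis stood at 98.6, and stem cell regulators (93.7), megakaryocyte (95.4), proliferation (87.6), T and NK cell (91.2) and sex-linked genes (74.6) fell within the range of random lists. Lists within the range on the main measure also left it. With the brightness trend removed, neutrophil genes stood at 99.9, glycolysis at 99.5, integrins at 99.4, cell cycle inhibitors at 99.3, AP-1 genes at 99.1 and Hox genes at 97.9. With normexp, glycolysis stood at 99.9, ribosome biogenesis at 97.6 and mast cell genes at 0.29, and near gene starts ribosome biogenesis stood at 100. Over probes well above background the same 6 lists as on the main measure lay above the range.

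At the main criterion the 1 gene belonged to 0 of 28 lists, so over-representation could not be tested there. At a log2 ratio of 2, Fisher's exact test, two-sided, found 0 lists over-represented (1 unadjusted). At a log2 ratio of 1, 7233 of 16655 genes counted as enriched, and depleted windows outnumbered enriched ones by 49283 to 27446. This direction turned with normexp (3403 against 37547) and with the brightness trend removed (15700 against 17342). In the main scaling 7 lists passed at a ratio of 1 (Fisher's exact test). They were stem cell regulators (adjusted p = 0.048), proliferation (0.046), cell cycle inhibitors (0.026), ribosome biogenesis (0.046), AP-1 (0.048), cholesterol synthesis (0.029) and glycolysis (0.046). Unlike the ranking, this test did not match genes on number of windows or input signal. Of these lists, cell cycle inhibitors, ribosome biogenesis, AP-1 and glycolysis lay within the range of matched random lists on the main measure. Mast cell and basophil genes were under-represented by the same test, with 2 of 18 genes (odds ratio 0.163, adjusted p = 0.046).

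**Figure D5:**
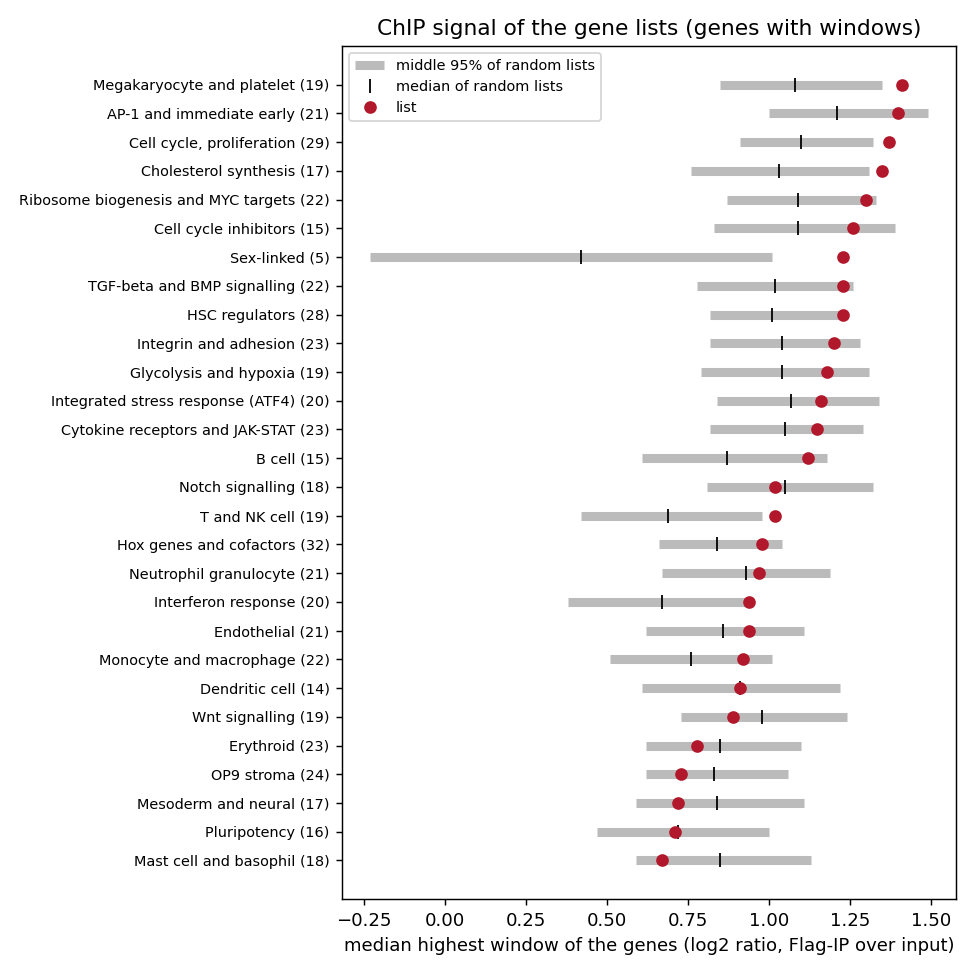
Median over each list's genes of the highest window (log2 ratio of Flag-IP over input, red points), with the median (tick) and the middle 95% (grey bar) of 10000 matched random lists. Numbers in parentheses count genes with windows, and 6 lists lie above their grey bar.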

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

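By a direct test 279 probe sets were higher and 140 lower in iHoxB4 than in HoxB4 (limma, adjusted p under 0.05). With only these 2 groups in the fit 250 and 158 passed, and with array weights 724 and 492. Leaving out either MigR1 array gives the same result as the fit of these 2 groups, since a lone array adds no spread, and is no further check. With any 1 HoxB4 or iHoxB4 array left out, or when tested for more than a ratio of 1.2, 0 and 0 passed, as with the replicate block, whose numbers are not taken to pair the arrays.

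Fewer probe sets passed against MigR1 in iHoxB4 (969) than in HoxB4 (3008). Without adjustment the counts were closer, 6027 in iHoxB4 and 7360 in HoxB4 (limma, p under 0.05). The fit pools the spread of all 6 arrays, with a median SE of 0.0149 on the log2 scale in both comparisons, so the counts follow the size of the changes, whose SD over probe sets was 0.0509 in iHoxB4 and 0.0665 in HoxB4. Of probe sets chosen as lower in HoxB4, 92.3% changed less in iHoxB4, which the choice favours. Of those chosen as lower in iHoxB4, 82.2% still changed more in HoxB4, but of those higher in iHoxB4 44.7% did. HoxB4 dose, doxycycline and the way HoxB4 was delivered were not tested and go with the group.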

How the results depend on the processing

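The score without log2, array weights, the crossed block, omission of the first run of probe sets and removal of the brightness trend were chosen after seeing the data. Counts are given as higher and lower, from limma, and where no cause is named the cause was not tested. Centring the arrays and a further quantile step left all 7 expression counts within 1.5 times the main ones. The arrays already had nearly the same distribution, so these steps could change little and do not check the normalization. HoxB4 against MigR1 kept calls in both directions except at a ratio of scores of at least 2, whereas iHoxB4 lost its calls under several settings. The excess of lower over higher calls in HoxB4 turned round with a variance trend, above the 50th percentile and without MigR1 array 1 (1742 and 1663). With 1 mean for each replicate number added (replicate block), HoxB4 against MigR1 gave 267 and 846, iHoxB4 against MigR1 0 and 0 (2299 and 2523 at an unadjusted p under 0.05), iHoxB4 against HoxB4 0 and 0 (1622 and 1393 unadjusted), and the overlap was 0. Same-numbered deviations correlated at 0.25 for MigR1 and HoxB4, -0.46 for MigR1 and iHoxB4 and -0.18 for HoxB4 and iHoxB4, so the numbers are not taken to pair the arrays. With the iHoxB4 numbers crossed in the block, iHoxB4 against MigR1 gave 48 and 320, iHoxB4 against HoxB4 86 and 40, and the overlap 348. With only the 2 groups compared, HoxB4 against MigR1 gave 213 and 747, iHoxB4 against MigR1 0 and 0 (2284 and 2536 unadjusted), iHoxB4 against HoxB4 250 and 158, and the overlap 0. Above the 50th percentile (fewer probe sets tested) HoxB4 against MigR1 gave 2147 and 2007, iHoxB4 against MigR1 gave 903 and 1227, iHoxB4 against HoxB4 582 and 303, and the overlap 1780. With a variance trend these were 2479 and 2200, 1299 and 1455, 718 and 331, and 2154. With no filter (more tested) they were 643 and 1266, 65 and 367, 156 and 67, and 401. With array weights they were 586 and 1157, 59 and 360, 724 and 492, and 388. Without log2, iHoxB4 was higher than MigR1 at 417. Without the first run of consecutive numbers iHoxB4 was higher than MigR1 at 428, and iHoxB4 against HoxB4 gave 440 and 260. A ratio of scores of at least 2, with adjusted p or with groups apart, left 1 probe set lower and 0 higher in HoxB4 against MigR1 and 0 for every other count. Tested for more than a ratio of 1.2 (limma treat), 4 were higher and 35 lower in HoxB4, and 0 in the others (iHoxB4 against MigR1 2 and 24 unadjusted, iHoxB4 against HoxB4 14 and 11). Single arrays left out, with the lone array taken to vary like the other groups, gave 94 to 1742 higher and 477 to 1716 lower for HoxB4 against MigR1, 0 to 328 and 0 to 667 for iHoxB4 against MigR1, 0 to 250 and 0 to 158 for iHoxB4 against HoxB4, and an overlap of 0 to 754.

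For ChIP-chip, normexp background correction gave 9102 regions and 7425 genes at its own threshold of 1.1. A fixed log2 ratio of 1 gave 8561 regions, 7233 genes and 7 over-represented lists (Fisher's exact test), and a fixed ratio of 2 gave 465 regions, 526 genes and 0 lists. With only probes well above background there were 2 regions and 2 genes, Atp6ap2 and Rtn4. The other settings gave 1 region and 1 gene, Atp6ap2, except that a median over 5 probes gave Rtn4. Not run, for want of gene names of probe sets, were the mean of all probe sets of a gene, the list tests on expression and the join of binding with expression. Both channels were well above background for 95.3% of probes. Over these probes depleted windows at a log2 ratio of 2 numbered 1549 in place of 5539, and enriched ones 914 in place of 1053. Depleted probes have a low Flag-IP signal relative to input, so the larger loss of depleted windows may come from the filter itself. The highest windows of genes over these probes correlated at 0.97 with the main ones.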

Other observations

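The brightness test of gene starts was chosen after the values were seen. Among 69 gene families sharing a symbol stem, picked out below after seeing the data, those of olfactory, vomeronasal and taste receptors ranked lowest against random lists. Over 846 olfactory receptor genes the median highest window was -0.09, against 0.57 in matched random lists, and 0 had a window at a log2 ratio of 2. Vomeronasal receptor genes had a median of -0.27 over 105 genes, taste receptor genes 0.13 over 36 and keratin-associated protein genes 0.11 over 33, whereas keratin (Krt) and collagen (Col) genes had 0.71 over 44 and 0.73 over 38, within the range of random lists. Ribosomal protein genes of the large subunit (Rpl) had a median of 1.42 over 48 genes and Mediator subunit genes (Med) 1.40 over 28, both at percentile 100 of their random lists. Of 1944 genes with a window at or below -2, 21.3% were olfactory receptors, which make up 5.08% of all genes. This share holds for the main scaling, with 5539 depleted windows of that size. Such windows numbered 45 with normexp and 231 with the brightness trend removed, for which the share is not given here. Mitochondrial probes had a median log2 ratio of -3.48 over 47 probes, with a median input signal of 64800 and a Flag-IP signal of 6770.

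Depleted windows outnumbered enriched ones at a log2 ratio of 2 by a ratio of 5.26. Dim spots as the whole cause are argued against, since the ratio stayed at 1.69 over probes well above background in both channels, although it fell. A dye bias that depends on brightness is a candidate explanation: the ratio fell to 0.662 once the median log ratio of probes of like brightness was removed. That step centres the probes of each brightness, which also takes out real enrichment of bright probes. It can lower the ratio for any cause tied to brightness, so the fall does not single out dye bias. After normexp correction the ratio was 0.0266. No biological explanation was tested.

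The log ratio at gene starts exceeded that far upstream by 0.77. A brighter input near starts as the whole cause is argued against, with a median difference of 0.75 over input quintiles, although it was 0.40 in the brightest, and the brightness trend as the whole cause likewise, with 0.36 left after its removal. A general property of active or CpG-rich starts, apart from HoxB4, stays open: olfactory receptor genes, silent in blood cells, differed by 0.66, but by 0.13 after the brightness trend was removed, against 0.36 for all genes, so the first value may reflect that trend. Sequence composition and an immunoprecipitation without the Flag tag were not analysed here.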
